A study of Homo sapiens with 6 samples.

How the data were processed

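Messenger RNA was sequenced from MCF-7 cells, an established human breast cancer line, 48 h after transfection with small interfering RNA. Per the labels, the libraries were made from total RNA with a stranded mRNA kit of Illumina, and 1 μg of RNA went into each. There were 6 libraries in 3 groups of 2, named siNC, siCDK4-1 and siCDK4-2 after the sample titles. The labels do not say what the numbers in siCDK4-1 and siCDK4-2 stand for, and both groups are called knockdown sets here. No label says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

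The deposited values are FPKM (fragments per kilobase of transcript, scaled to library depth), given with 2 decimals for 59146 genes and 210946 transcripts, per the file headers and the labels. The submitters' processing notes name STAR, HTSeq, DESeq2 and the build hg38, with no versions or roles, and how each gave the FPKM values is not given in the sources used here. Of the gene rows, 58233 have an Ensembl ID and 913 have only an assembly ID and no gene name. The length column of the transcript table, also deposited, was used as transcript length in bases. Gene values equal the sum of the FPKM of the gene's transcripts within 0.05 FPKM for 100% of values, over 56358 genes. FPKM values carry how fragments were shared between overlapping or near-identical transcripts, which cannot be undone here, so a gene can be listed at 0 in one library and well above it in another. Sums of FPKM per library ranged from 933538 to 1061490.

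Sequencing depth was fitted from the low values. For genes with 1 transcript of 400 to 800 bases, low FPKM values fall on steps that depend on transcript length and depth. The fit gave 25.0 to 27.6 M fragments per library, and 88.4 to 91.0% of low values were then within 0.1 of a whole number of fragments, against 20% by chance. On simulated values its largest error was 3.33%. Whole counts were not recovered for longer or multi-transcript genes, and no count test was run.

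Genes with at least 1 FPKM in at least 2 of the 6 libraries were tested, which left 15626. Values were taken as log2(FPKM + 1), so a log2 change understates the change of low genes. A model with the 3 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend on mean level). The contrasts taken from it were the mean of both knockdown sets minus siNC, each set minus siNC, and siCDK4-2 minus siCDK4-1. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. Log2 changes are given with the standard error (SE) of the fit. FPKM levels are means ± SD of 2 libraries. Tested on simulated data with 200 changed genes in 20 draws, the contrast of both sets recovered 51.5% of genes changed by log2 1 and 94.9% of those changed by log2 2, and 5.84% of its calls were false. For siCDK4-1 alone these shares were 35.4% and 89.7%, and for siCDK4-2 alone 34.9% and 89.6%. These changes were alike in both sets, so the test between the sets had none to find (0.2 calls on average). With changes put into siCDK4-2 only, that test recovered 34.0% and 88.9%, and 5.18% of its calls were false.

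Genes were named by a rule. CDK4 is always named. Among genes past the threshold in both sets together and in each set with the same sign, the 12 with the largest change each way are named. Between the sets, the 8 largest each way are named. Of each gene list, up to 4 members past the threshold are named, or up to 2 with the highest level if none passed, and all members of 2 lists (cyclins and kinases, and genes next to CDK4) may be named. Clone-based names were left out. Other genes are said to have been chosen after their values were seen.

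A set of 29 gene lists with 616 entries was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. All entries but 1 were found in the file, and older symbols were matched through a table of gene names. Alternatives were camera with an estimated correlation and fry. The first rests on the 3 residual degrees of freedom of the fit, so a list could pass the threshold only with a very large statistic. On simulated data, a list of 27 genes shifted by log2 0.5 was called in 20 of 20 draws. For genes called in both sets, 100 draws of unchanged groups against the same controls gave the overlap expected without any effect.

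Other settings tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, scaling to TPM, median-ratio scaling, quantile normalization, the replicate number as a block, no trend in eBayes, leaving out each library, sums over the transcript table, an added limit of log2 1, the knockdown libraries as 1 group, and only the 4 libraries compared. The groups, tests, lists, naming rule and these alternatives were fixed before the data were examined. Leaving out genes with only an assembly ID, the split of the siNC libraries between the sets and the simulated change in 1 set were added after seeing the data. Gene positions are from GENCODE release 29 (GRCh38, which is hg38), looked up by Ensembl ID.

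For the closing part, genes with at most 0.1 FPKM in a pair of libraries and at least 2 FPKM in the other 4, or the reverse, were counted for every pair. The trend of log2 change on transcript length, in 60 bins, was removed from the histone genes, and the median change of small RNA types was bootstrapped 10000 times. Also, 3′ untranslated regions (3′ UTRs) were taken from the most abundant coding transcript of each tested gene in GENCODE 29, with a minimum of 50 bases, which gave 11393 genes without CDK4. The presence of each of 16146 words of 7 bases, found in at least 50 genes, was regressed against the log2 change, with terms for UTR length and GC content, and adjusted over the words. On simulated data a word that lowered its genes by log2 0.3 ranked first in 10 of 10 draws, and 0 of 10 shuffled data sets gave a call. Gene Ontology terms of 10 to 500 genes, from the annotation in the deposited table, were tested with the hypergeometric distribution against tested genes with a term. These steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.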

Results

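Gene expression was measured by RNA sequencing in MCF-7, a luminal breast cancer cell line that expresses the oestrogen receptor, 48 h after transfection of small interfering RNA. The series addresses the effect of depleting CDK4, the kinase that pairs with D-type cyclins and phosphorylates the RB protein in G1. There were 2 libraries with control RNA (siNC), 2 of the knockdown set siCDK4-1 and 2 of siCDK4-2. Fitted depth, in M fragments, was 25.4 and 26.0 in siNC, 25.0 and 27.6 in siCDK4-1, and 26.4 and 25.8 in siCDK4-2. Between 14451 and 14912 genes reached 1 FPKM per library. Correlations of log2 values across genes were 0.9716 to 0.9764 within the 3 groups and 0.9573 to 0.9725 for the 12 pairs of libraries from different groups. The ranges thus overlap slightly. Mitochondrially encoded transcripts made up 9.89 and 9.11% of FPKM in siNC, 12.7 and 9.91% in siCDK4-1, and 10.9 and 10.6% in siCDK4-2, so all 4 knockdown libraries were above both controls.

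CDK4 itself was measured first, since it checks the labels. CDK4 (ENSG00000135446, chromosome 12, 57747727 to 57756013, minus strand) stood at 156.23 and 176.82 FPKM in the siNC libraries. It stood at 23.46 and 25.26 FPKM in siCDK4-1 and at 27.13 and 32.3 FPKM in siCDK4-2. On the log2 scale CDK4 fell by 2.59 over both sets (SE 0.12, adjusted p = 0.00169 in limma), by 2.72 in siCDK4-1 (adjusted p = 0.00307) and by 2.45 in siCDK4-2 (adjusted p = 0.00403). The 2 sets differed by 0.27 (SE 0.13, adjusted p = 0.446), which is not past the threshold. Leaving out either siCDK4-1 library gave an adjusted p of 0.0562 or 0.0513 for both sets, with log2 changes of -2.56 and -2.61. The largest single part of CDK4 signal in each library lay on a transcript of 2019 bases that carries an assembly ID, at 113.21 and 139.64 FPKM in siNC and between 12.97 and 19.93 FPKM in the knockdown libraries. In siCDK4-2 replicate 2 it made up 13.48 of 32.3 FPKM. The gene TSPAN31 overlaps CDK4 on the other strand (chromosome 12, 57738013 to 57750211), and its level was 23.1 ± 1.02 FPKM in siNC, 25.8 ± 2.26 in siCDK4-1 and 30.4 ± 5.18 in siCDK4-2 (log2 0.26, adjusted p = 0.378). None of the 7 tested genes next to CDK4 passed the threshold in both sets together. Among them, MARCH9 and METTL1 differed from siNC by 0.03 and 0.01, AGAP2 by -0.27, CYP27B1 by 0.22, EEF1AKMT3 by -0.02 and TSFM by -0.16 on the log2 scale.

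**Figure D1:**
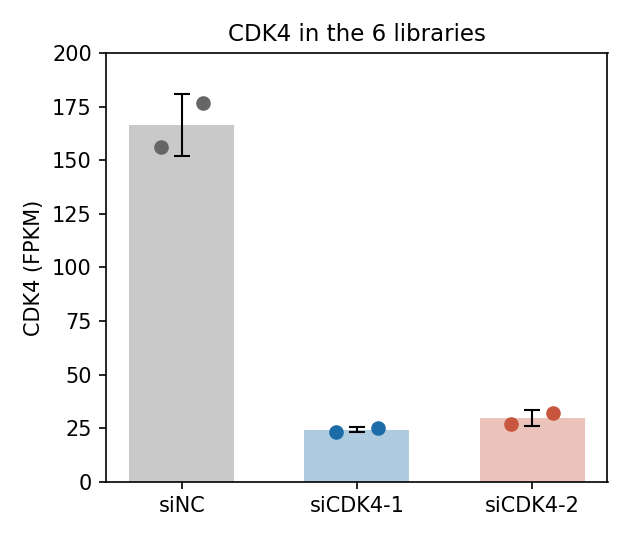
CDK4 level (FPKM) in siNC, siCDK4-1 and siCDK4-2, 2 libraries each. Points are libraries, bars are means and error bars are SD; the 4 knockdown libraries lie between 23.46 and 32.3 FPKM, below both siNC libraries at 156.23 and 176.82.

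The comparison of both knockdown sets with siNC asked what changed with less CDK4. The 12 named genes that fell furthest in both sets were CDK4, 8 genes of DNA replication and cell division, and TMEM160, PKMYT1 and ITGB1. Replication genes were CDT1 and CDC6, which load the MCM helicase onto origins, CDC45, which activates it, and MCM7, one of its subunits. CDT1 (chromosome 16, 88803213 to 88809258) went from 62.59 and 60.89 FPKM in siNC to 17.68 and 26.25 in siCDK4-1 and 22.77 and 20.46 in siCDK4-2, and fell by 1.47 (SE 0.17, adjusted p = 0.0269). MCM7 (chromosome 7, 100092728 to 100101940), the host gene of 3 microRNAs, went from 116 ± 13.1 FPKM to 47.0 ± 2.84 and 39.9 ± 2.92, and fell by 1.40 (SE 0.11, adjusted p = 0.0160). The changes of CDC45 and CDC6 were -1.46 and -1.42. Division genes were ANLN, the cytokinesis scaffold anillin (-1.60), CENPK and SPC24 of the kinetochore (-1.57 and -1.56), and CDCA5, the cohesin regulator sororin (-1.50). PKMYT1, a kinase that inhibits CDK1, changed by -1.53 and ITGB1, the integrin beta 1 subunit, by -1.47. TMEM160, a small transmembrane protein (chromosome 19, 47045907 to 47048630), fell by 1.87, from 30.2 ± 3.15 FPKM to 11.6 ± 0.467 and 4.76 ± 0.778.

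Fewer genes rose. The 12 named ones were led by HERC3, a HECT-type ubiquitin ligase (chromosome 4, 88592423 to 88708542), at 2.20 ± 0.714 FPKM in siNC, 15.9 ± 0.403 in siCDK4-1 and 17.1 ± 4.48 in siCDK4-2 (log2 2.46, SE 0.21, adjusted p = 0.0160). Its rise lay on 1 transcript of 1298 bases that is listed at 0 in both siNC libraries and at 11.83 to 16.86 FPKM in the knockdown libraries. Its transcript of 4974 bases was at 0.99 and 0.93 FPKM in siNC and at 0.72, 0.38, 0.43 and 0.23 FPKM in the knockdown libraries. Another of 4764 bases went the other way, from 0 and 0.26 FPKM in siNC to 0.28, 0.65, 1.04 and 0.77 FPKM. How fragments were shared between HERC3 transcripts is uncertain. SLC7A8, an amino acid transporter, rose by 1.35 and CASP7, an executioner caspase, by 1.09, from 6.59 ± 0.262 FPKM to 16.1 ± 1.08 and 14.3 ± 0.615. TPM4, a tropomyosin, rose by 1.05, GOLT1A, a Golgi transport protein, by 0.98, AES, a transcriptional co-repressor, by 0.85, and ZDHHC16, a palmitoyltransferase, by 0.84. NOLC1, a nucleolar phosphoprotein, rose by 0.82 and SULT1A1, a sulfotransferase with close paralogs, by 0.81. The remaining 3 were the histone genes HIST1H4H, HIST1H2BD and HIST1H3H.

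In all, 215 of 15626 genes passed an adjusted p of 0.05 in limma, 51 higher and 164 lower, and 2783 had an unadjusted p under 0.05. The smallest adjusted p belonged to AC006435.4, a short transcript inside METTL16, listed at 0.03 and 0 FPKM in siNC, 77.4 and 68.16 in siCDK4-1, and 120.76 and 147.38 in siCDK4-2. Of the 215, 211 had the same sign in both sets. Calling genes on the mean of both sets favours this, as do the shared siNC libraries. When each set was tested alone, 53 of them passed in both, 42 in siCDK4-1 only, 81 in siCDK4-2 only and 39 in neither, and 25 also differed between the sets. The count rests on all 6 libraries: leaving out 1 library gave 1 to 27 genes. It was 2 with no filter on low values, 362 with a filter of 5 FPKM and 10 without a trend in the variance.

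Of 36 genes of the list of G1/S and E2F targets, 16 fell (33 adjusted over the list alone) and none rose, with a median log2 change of -0.84. Besides CDT1, CDC45 and CDC6, RRM2, a subunit of ribonucleotide reductase, fell by 1.40, from 79.54 and 116.94 FPKM in siNC to 28.22 and 31.75 in siCDK4-1 and 49.66 and 36.98 in siCDK4-2. Of 30 genes of G2/M and mitosis, 14 fell (28 adjusted over the list alone), with a median of -0.95. CDK1, the mitotic kinase (chromosome 10, 60778331 to 60794852), fell by 1.34, AURKB by 1.32 and KIF2C, a kinesin that depolymerises microtubules, by 1.30. Among 19 genes of homologous recombination and the Fanconi pathway, 5 fell (16 adjusted over the list alone), with a median of -0.86. They included RAD54L (-1.53), the recombinase RAD51 (-1.30), the nuclease EXO1 (-1.28) and RMI2 (-1.15). Camera called these 3 lists with adjusted p of 7.57e-28, 9.39e-28 and 9.57e-14 at the preset correlation. With an estimated correlation they were not called, at adjusted p = 0.108, 0.165 and 0.108, while fry gave 0.00643, 0.0160 and 0.00763.

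The list of cyclins, CDKs, CDK inhibitors and RB family genes held 19 tested genes, of which 1 fell over all genes and 6 adjusted over the list alone (median -0.31, camera adjusted p = 0.00495, adjusted p = 0.381 with an estimated correlation, and 0.0612 in fry). The gene that fell was CDKN2D, the CDK4 and CDK6 inhibitor p19, at 36.3 ± 0.863 FPKM in siNC, 15.5 ± 1.65 in siCDK4-1 and 20.5 ± 1.89 in siCDK4-2 (log2 -0.99, adjusted p = 0.0286). For members that did not pass, the log2 values were -0.66 for CDK2, -0.86 for CCNE2, -0.77 for CDC25A, -0.61 for CDKN1B and -0.45 for CDKN2C. CCND1 was at -0.32, CCNE1 at 0.18, CDKN1A at -0.23, RB1 at 0.02 and E2F3 at 0.00. For this list, the call was also lost with a filter of 5 FPKM (adjusted p = 0.0866), and the median was -0.19 without siCDK4-2 replicate 2.

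Of 11 tested histone genes of the clusters, 5 rose (10 adjusted over the list alone) and none fell, with a median of 0.90 (camera adjusted p = 5.9e-10, adjusted p = 0.165 with an estimated correlation, and 0.015 in fry). HIST1H4H (chromosome 6, 26277609 to 26285638) went from 1.69 ± 0.0424 FPKM to 10.9 ± 1.61 and 8.12 ± 2.90, and rose by 1.93 (SE 0.22, adjusted p = 0.0269). HIST1H2BD (chromosome 6, 26158146 to 26171349) rose from 28.4 ± 9.36 FPKM to 80.4 ± 5.76 and 79.9 ± 5.61 (adjusted p = 0.0286), HIST1H3H (chromosome 6, 27810064 to 27811300) by 1.08 and HIST1H2AC (chromosome 6, 26124145 to 26139116) by 1.02. Histone genes have near-identical copies, so how fragments were shared between copies is uncertain.

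**Figure D2:**
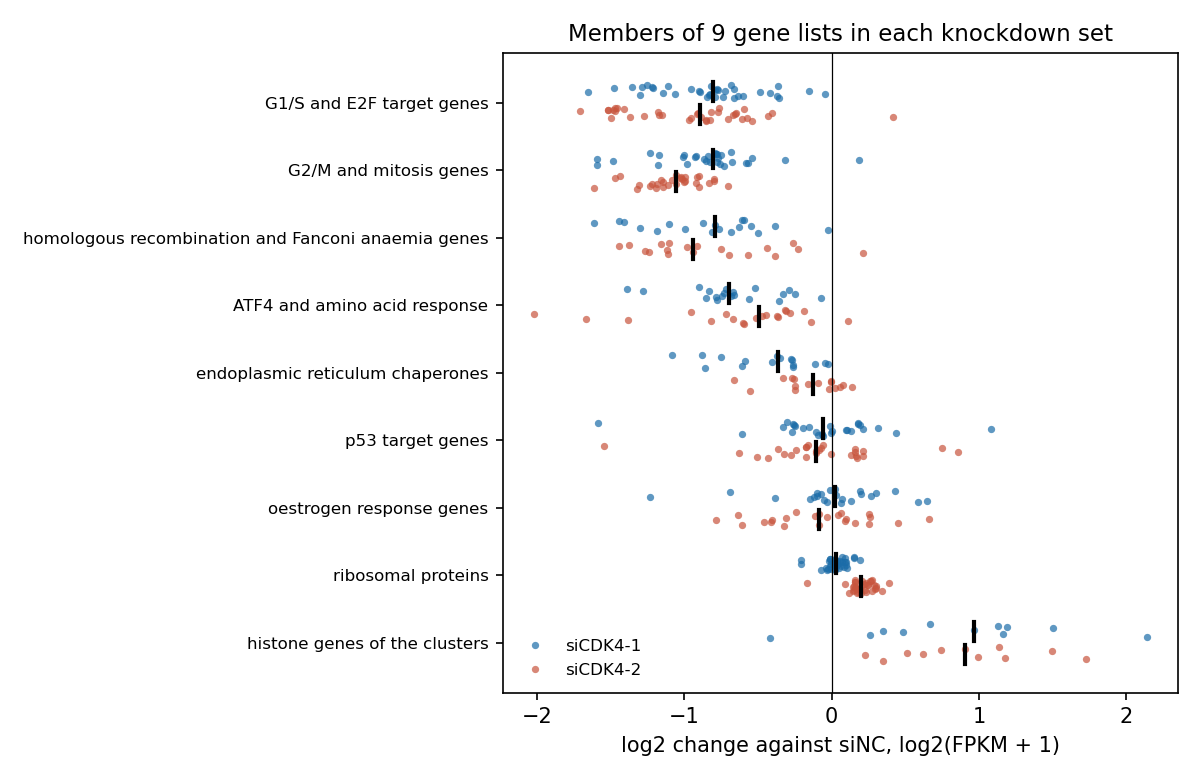
Log2 change against siNC, on the log2(FPKM + 1) scale, of each tested member of 9 gene lists in siCDK4-1 (blue) and siCDK4-2 (red). Points are genes and black bars are list medians; the medians of the G1/S list are -0.81 and -0.89, and those of the histone list are 0.96 and 0.91.

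Of 20 genes of the ATF4 and amino acid response, 2 fell (14 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 2.66e-11, adjusted p = 0.467 with an estimated correlation, and 0.102 in fry). PSAT1, an enzyme of serine synthesis, fell by 1.65, from 45.8 ± 10.5 FPKM to 18.3 ± 4.42 and 10.5 ± 2.18, and the transcription factor CEBPB by 0.83. Of 16 chaperones of the endoplasmic reticulum, SDF2L1 (-0.71) and HSPA5, which encodes BiP (-0.61), fell (3 adjusted over the list alone; median -0.22, camera adjusted p = 8.46e-05, and adjusted p = 0.165 with an estimated correlation). Alone, siCDK4-1 had a median of -0.36 for these chaperones (camera adjusted p = 1.08e-07, and 0.113 with an estimated correlation) and siCDK4-2 one of -0.13 (0.0990, not called). HSPA5 fell by 0.88 in siCDK4-1 and was at -0.33 in siCDK4-2 (adjusted p = 0.172), and SDF2L1 passed in neither set alone. Of 23 genes of cholesterol synthesis 1 fell, the sterol oxidase MSMO1 (-0.67), and adjusted over the list alone 1 fell and 1 rose (median -0.25, camera adjusted p = 0.00286, adjusted p = 0.165 with an estimated correlation, and 0.0794 in fry). Only siCDK4-1 alone gave a call for cholesterol synthesis (median -0.31, camera adjusted p = 4.23e-05, not called with an estimated correlation), with -0.16 and 0.269 in siCDK4-2. MSMO1 fell in siCDK4-1 (-1.14) and not in siCDK4-2 (-0.21, adjusted p = 0.432).

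Camera called 5 more lists in which no member passed over all genes. The 13 mitochondrially encoded mRNAs all had positive values, with a median of 0.34 (camera adjusted p = 0.000486, and adjusted p = 0.576 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, was at 12854 ± 1714 FPKM in siNC, 16973 ± 4397 in siCDK4-1 and 16851.5 ± 1807 in siCDK4-2. The median was 0.10 for 35 ribosomal protein genes (adjusted p = 0.852 with an estimated correlation), and quantile normalization ended that call (adjusted p = 0.820). Alone, siCDK4-2 was called, at 0.20 (camera adjusted p = 4.25e-05, and 0.592 with an estimated correlation), and siCDK4-1 was not, at 0.03 (0.917). Between the sets, this list was called by camera at the preset correlation (adjusted p = 4.67e-05). It was not called with an estimated correlation (adjusted p = 0.924) or by fry (adjusted p = 0.543). For 17 NRF2 targets the median was -0.11 (4 lower adjusted over the list alone, adjusted p = 0.563 with an estimated correlation). Here too siCDK4-2 alone was called, at -0.24 (camera adjusted p = 0.00103, and 0.423 with an estimated correlation), while siCDK4-1 was at 0.05 (0.593). For 18 genes of fatty acid synthesis it was -0.09 (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.538 with an estimated correlation). Only COL1A1 and ACTA2 were tested of the fibroblast and endothelial markers, at 0.53 and 0.55 (both higher adjusted over the list alone, adjusted p = 0.364 with an estimated correlation). Leaving out at least 1 of the libraries in turn ended the call of each of the last 4 lists.

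The other 16 lists were not called by camera, with adjusted p of 0.242 to 0.966. Of 27 p53 targets, BTG2, an anti-proliferative gene, rose by 0.97 and none fell (1 higher and 2 lower adjusted over the list alone; median -0.12). Of 23 oestrogen response genes, XBP1, a transcription factor of the unfolded protein response, fell by 0.66 (1 adjusted over the list alone; median -0.0021). CASP7 was the gene that rose among 18 BCL2 family and caspase genes (median -0.01) and NOLC1 among 21 of ribosome biogenesis (median -0.09). No member passed over all genes in the rest. Medians were -0.02 for luminal markers (1 higher and 5 lower adjusted over the list alone), 0.01 for basal markers, 0.12 for interferon-stimulated genes, -0.09 for MHC class I (2 lower adjusted over the list alone), -0.01 for NF-kB genes and -0.0030 for glycolysis. They were -0.07 for hypoxia, 0.05 for the nuclear-encoded respiratory chain (1 higher adjusted over the list alone), -0.04 for cytosolic heat shock proteins, -0.05 for lysosome and autophagy, 0.01 for genes next to CDK4 and 0.02 for 3 leukocyte markers. KRT8 and KRT18, the most abundant luminal markers, were at 0.14 and 0.19, from -0.08 and -0.11 in siCDK4-1 and 0.37 and 0.49 in siCDK4-2, none past the threshold. In single sets, camera called luminal markers lower in siCDK4-1 only (median -0.14, adjusted p = 0.0119, and 0.400 with an estimated correlation). It called basal markers, of which 9 of 19 were tested, higher in siCDK4-2 only (median 0.23, adjusted p = 0.0384, and 0.417 with an estimated correlation). In the lists of BCL2 and caspase, NF-kB, glycolysis, hypoxia and leukocyte genes, the median, the mean and the direction in camera differed in sign. Over the 29 lists, camera called 13 at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry called 7. The estimated correlation was 0.012 for chaperones of the endoplasmic reticulum and -0.019 for cholesterol synthesis, near or under the preset 0.01. Both lists still lost their call, so larger correlations do not account for the loss there. The estimate was far larger for the ATF4 list (0.74), mitochondrially encoded mRNAs (0.71), ribosomal proteins (0.67) and G2/M genes (0.34). For these, the calls at the preset correlation rest on a value well under the estimate. Of these, fry called only the G2/M list. With so few degrees of freedom, the 0 calls alone do not argue against the lists called at the preset correlation. One of the 7 lists called by fry was that of NF-kB genes, as higher (adjusted p = 0.0267), with only 5 of its 24 genes tested. Camera did not call it (adjusted p = 0.829, and 0.939 with an estimated correlation). In single sets fry called that list lower in siCDK4-1 (adjusted p = 0.0457) and higher in siCDK4-2 (adjusted p = 0.00365).

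Each knockdown set was then compared with siNC on its own. In siCDK4-1, 139 genes passed the threshold, 30 higher and 109 lower. LAPTM4A, a lysosomal membrane protein, fell by 1.98 in that set, TAF13, a subunit of the general transcription factor TFIID, by 1.68, and RRM2 by 1.66. Of the G1/S list 7 genes fell, and of the G2/M list 5. In siCDK4-2, 205 genes passed, 53 higher and 152 lower. TMEM160 fell by 2.44 there and PSAT1 by 2.02, and 15 genes of the G1/S list and 14 of the G2/M list fell. Counts of unadjusted p under 0.05 were 2470 and 2750. Leaving out 1 library gave 1 to 75 genes in siCDK4-1 and 2 to 13 in siCDK4-2, and a fit to only the 4 libraries compared gave 63 and 2.

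A total of 53 genes passed in both sets with the same sign, 17 higher and 36 lower. Both comparisons use the same siNC libraries, which alone makes them alike. Unchanged groups simulated against these controls gave a mean of 0.01 such genes and at most 1, and independent lists of the observed lengths would share 1.16. The simulated groups held no change in either set, so few calls of any kind could arise there. That number therefore does not show how many genes sets with unlike changes would share. Across genes the log2 changes of the sets correlated with r = 0.58, against 0.50 in simulated unchanged groups, where genes are not independent replicates. Their covariance was 0.115 against a mean of 0.0487 and at most 0.0541 simulated, and 69.0% of genes had the same sign against 66.7%. With 1 siNC library for each set, so that none was shared, r was 0.21 or 0.29 and the covariance 0.0545 or 0.0702, by which library went to which set. The called genes could not be recounted with 2 controls for each set, so part of their excess may come from shared controls. Without any 1 of the libraries, 1 to 8 genes passed in both sets. Some of these genes also carry words of 7 bases in their 3′ UTRs that went with lower values in one set, as described for the difference between the sets.

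The difference between the sets was tested directly. LAPTM4A (chromosome 2, 20032650 to 20052028) was at 287 ± 9.31 FPKM in siNC, 71.9 ± 2.49 in siCDK4-1 and 257 ± 27.0 in siCDK4-2, a difference of 1.82 between the sets (adjusted p = 0.00816). SSR3, a subunit of the translocon-associated complex of the endoplasmic reticulum (chromosome 3, 156540140 to 156555184), was at 154 ± 16.5, 54.4 ± 3.90 and 216 ± 29.5 FPKM, a difference of 1.96. BEX3, TAF13 and TMEM35B were also higher in siCDK4-2, by 2.09, 1.94 and 2.31. CYP24A1, the vitamin D 24-hydroxylase, was at 3.01 ± 0.0283 FPKM in siNC, 3.26 ± 0.339 in siCDK4-1 and 14.7 ± 5.27 in siCDK4-2, a difference of 1.85. Lower in siCDK4-2 were SLC39A1, a zinc transporter (chromosome 1, 153959099 to 153968184), at 133.47 and 143.58 FPKM in siNC, 130.78 and 147.75 in siCDK4-1, and 45.05 and 43.02 in siCDK4-2 (-1.64, adjusted p = 0.00934), PPP1CC, a catalytic subunit of protein phosphatase 1 (-1.48), TOMM5, a subunit of the mitochondrial import pore (-1.39), and BMI1, a Polycomb protein (-1.37). KCNE4, TMEM150C and the non-coding RNA H19 were lower by 1.68, 1.35 and 1.34. SMIM11B, which has a near-identical copy, SMIM11A, was lower by 3.21, with 0 and 0.69 FPKM in siCDK4-2. RNU1-106P, an snRNA copy inside PVT1, and VENTXP2, a pseudogene, were listed at 0 in all siNC and siCDK4-1 libraries, and at 17.34 and 17.79 FPKM and at 6.99 and 7.80 FPKM in siCDK4-2.

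**Figure D3:**
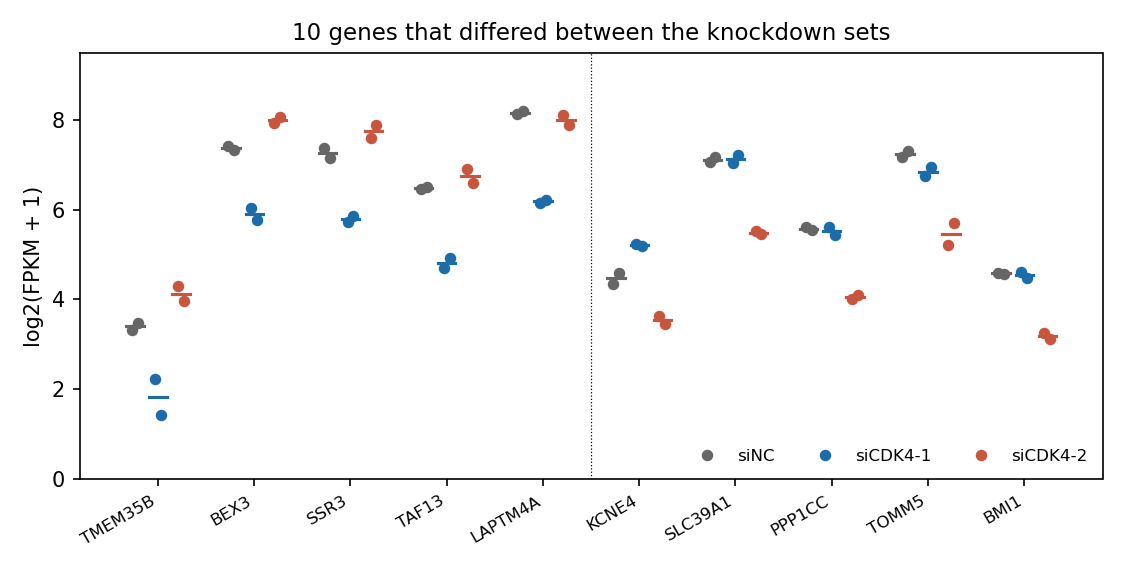
Level, as log2(FPKM + 1), of 10 genes that differed between the knockdown sets, in siNC (grey), siCDK4-1 (blue) and siCDK4-2 (red). Points are libraries and bars are means of 2. The 5 genes left of the dotted line were lower in siCDK4-1 than in siCDK4-2 and the 5 on the right were lower in siCDK4-2. In their 3′ UTRs, the 5 on the left hold the word GCCTTTA and the 5 on the right GGACATA, as described in the text. Named genes without either word, such as CYP24A1, SMIM11B and TMEM150C, are not shown.

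In total 86 genes differed between the sets, 58 higher and 28 lower in siCDK4-2, and 2043 had an unadjusted p under 0.05. Of the 58, 38 also fell in siCDK4-1 against siNC. Leaving out 1 library gave 0 to 7 genes, and a fit to only the 4 libraries of these sets gave 7. Of the 12 named genes lower in both sets, the 3′ UTR of ANLN holds the words GCCTTTA and GGACATA, which went with lower values in siCDK4-1 and in siCDK4-2 across 11393 genes. That of ITGB1 holds the first and that of SPC24 the second, and RRM2 and KIF2C also hold the first. HIST1H2BD and TPM4 hold another word, CGGAGAA, which went with higher values in both sets against the same siNC libraries. Camera called 7 lists between the sets and none with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 1, the NF-kB genes (adjusted p = 0.00161, against 0.222 in camera). No member of the G1/S list and no member of the G2/M list passed in this test.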

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

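Of the tests in this part, the count of genes absent in a pair of libraries and the test of scaling were chosen only after the result was seen. What drew attention here was a difference between the knockdown sets by its own test in limma. It covers 86 genes. On the log2 scale, siCDK4-2 minus siCDK4-1, the named genes were RNU1-106P (4.21), VENTXP2 (3.07), TMEM35B (2.31), BEX3 (2.09), SSR3 (1.96), TAF13 (1.94), CYP24A1 (1.85), LAPTM4A (1.82) and MSMO1 (0.94). Lower in siCDK4-2 were SMIM11B (-3.21), KCNE4 (-1.68), SLC39A1 (-1.64), PPP1CC (-1.48), TOMM5 (-1.39), BMI1 (-1.37), TMEM150C (-1.35) and H19 (-1.34). Among the lists, camera at the preset correlation called a difference for G2/M genes (median -0.21), luminal markers (0.25), basal and mesenchymal markers (0.57), cholesterol synthesis (0.18), chaperones of the endoplasmic reticulum (0.28), NRF2 targets (-0.20) and ribosomal proteins (0.18). With an estimated correlation none of these was called, and the smallest adjusted p was 0.376.

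A candidate explanation for genes lower in one set is silencing of other transcripts that match the seed of that set's duplex, whose sequences are not in the labels. If so, a 7-base word of the CDK4 mRNA should be the word most tied to lower values, and this was predicted before the scan was run. For siCDK4-1 the word with the lowest statistic of 16146 was GCCTTTA (t = -22.49, adjusted p = 1.85e-105), which occurs in the CDK4 mRNA from base 1350, and genes with it were lower by 0.275 in siCDK4-1 and differed by 0.003 in siCDK4-2. Of the 49 genes lower in siCDK4-1 than in siCDK4-2 that have a 3′ UTR, 31 hold it. LAPTM4A, SSR3, BEX3, TAF13 and TMEM35B are among them, while CYP24A1 and MSMO1 do not hold it. The same libraries picked the word, so this count describes these genes and is no further test. Scaling of the libraries does not account for most of this side. Of the 58 genes higher in siCDK4-2, 41 stayed called under TPM scaling, 58 under median-ratio scaling and 57 under quantile normalization. It may bear on the genes that lost their call under TPM scaling.

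For siCDK4-2 the lowest word was GGACATA (t = -11.04, adjusted p = 5.64e-24), which occurs in the CDK4 mRNA from base 668. Genes with it were lower by 0.184 in siCDK4-2 and by 0.013 in siCDK4-1. Of 24 genes lower in siCDK4-2, 10 hold it, among them SLC39A1, PPP1CC, TOMM5, BMI1 and KCNE4, and this too restates the scan. SMIM11B and TMEM150C do not hold it. Of the words tested, 11.4% occur in the CDK4 mRNA, so each match alone could be chance at about that rate. Both results are consistent with seed-matched effects that differ by set, and a shared effect of less CDK4 on genes without the words remains open.

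Some of the genes that differ most are listed at 0, namely RNU1-106P and VENTXP2 in all siNC and siCDK4-1 libraries and SMIM11B in 1 siCDK4-2 library. AC006435.4, chosen after its values were seen, is listed at 0.03 and 0 FPKM in siNC and lies inside METTL16 (chromosome 17, 2424179 to 2424412). A candidate explanation is that fragments were assigned differently between overlapping or near-identical transcripts. At most 0.1 FPKM in both siNC libraries and at least 2 FPKM in the other 4, or the reverse, was found for 5 genes. The same count was 5 for the siCDK4-1 pair, 6 for the siCDK4-2 pair, and 1 to 7 (median 2.5) for the 12 pairs of libraries that are not a group, 2 of which had at least 5. Such genes thus also arise between libraries of different groups. Mixed pairs from siCDK4-1 and siCDK4-2, which share the CDK4 knockdown, had 1 to 4. Most mixed pairs had fewer than the groups, so whether a given gene follows treatment or assignment stays open.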

How the results depend on the processing

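Leaving out genes with only an assembly ID was chosen after seeing the data. No named gene or list past its threshold changed sign under the settings run, nor did CDK4, but counts moved widely. In the order both sets, siCDK4-1, siCDK4-2, difference between sets, and same way in both sets, the main counts were 215, 139, 205, 86 and 53. With no filter on low values (29315 genes tested) they were 2, 1, 1, 0 and 1. With 5 FPKM required (10357 genes) the first 2 were 362 and 235 and the last 2 were 155 and 96. Without a trend they were 10, 7, 14, 13 and 3. Requiring log2 1 left 108 for both sets and 133 for siCDK4-2. Taking the knockdown libraries as 1 group gave 106, and only the 4 libraries compared gave 63, 2 and 7 for siCDK4-1, siCDK4-2 and the difference. Quantile normalization gave 132 for siCDK4-2. The cause of these moves was not tested, beyond the number of genes tested or samples used that each setting changes. All counts stayed within 1.5 times the main ones with a pseudocount of 0.1, TPM or median-ratio scaling, summed transcripts, and assembly genes left out. Summed transcripts repeat the gene values within 0.05 FPKM over fewer genes, so that setting is no separate check. TPM scaling moved the median difference between the sets over all genes to -0.11, from -0.04.

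Leaving out each library in turn gave 1 to 27 genes for both sets, 1 to 75 for siCDK4-1, 2 to 13 for siCDK4-2, 0 to 7 for the difference and 1 to 8 in both sets. The lone library of a group was then assumed to vary like the other groups. For both sets, 1 gene was called without either siCDK4-1 library, 9 and 3 without siNC replicate 1 and 2 (4 and 2 of them among the 215), and 21 and 27 without siCDK4-2 replicate 1 and 2 (18 and 26 among them). For siCDK4-1, 71 and 75 were called without a siCDK4-2 library (66 and 69 among the 139) and 1 to 5 without another. Between the sets, 7 were called without either siNC library or siCDK4-2 replicate 1 (6, 6 and 4 among the 86), and 0 without another. The log2 change of CDK4 ranged from -2.67 to -2.50, and its adjusted p over the settings from 0.000656 to 0.0562.

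Replicate numbers as given did not pair the samples. The correlations of deviations were 0.14 for siNC and siCDK4-1, -0.19 for siNC and siCDK4-2, and -0.14 for siCDK4-1 and siCDK4-2. With the siCDK4-2 numbers swapped, all of these would be positive. A pairing of that kind was not fitted, so a structure shared across the groups is not excluded. With the number as given as a replicate block the counts were 5, 5, 12, 0 and 2, and CDK4 stayed called (adjusted p = 0.00688 in limma). Camera called 13 lists as main, 0 with an estimated correlation and 7 in fry. It called 9 to 13 in the settings that kept camera's preset correlation.

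Values that were not past the threshold did change sign, in 13 of 16 lists and 16 of 57 gene results. The median of luminal markers went from -0.02 to 0.06 without siCDK4-2 replicate 2, that of oestrogen response genes from -0.0021 to 0.04 without siNC replicate 2, and that of basal markers from 0.01 to -0.03 under TPM scaling. With CDK4 over both sets aside, 58 gene results were past the threshold. All 58 lost it with no filter, 55 under the block, 46 without a trend and 44 to 58 without 1 library. With 25.0 to 27.6 M fragments and a median residual SD of 0.189 on the log2 scale, 51.5% of changes of log2 1 were found in simulated data for both sets, and 35.4 and 34.9% for siCDK4-1 and siCDK4-2 alone.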

Other observations

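The tests of histone genes were fixed after their rise was seen but before the tests were run, and the tests of Gene Ontology terms and of lists without the words were chosen after. Among the 164 genes lower over the mean of both sets, 129 had a Gene Ontology process, and 25 terms were enriched. DNA replication held 15 of them, out of 95 tested genes (adjusted p = 6.2e-09), the G1/S transition 11 of 49 (adjusted p = 4.5e-08), and initiation of replication 8 of 22 (adjusted p = 1.33e-07). Cell division held 18 of 207 and sister chromatid cohesion 9 of 63. Among the 51 genes higher over that mean 30 had a term, and nucleosome assembly was the one enriched (4 of 57, adjusted p = 0.0450). No term was enriched among genes that differed between the sets, with 35 and 12 annotated genes.

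Over all 11393 genes with a 3′ UTR, 8.97% held GCCTTTA and 4.96% GGACATA. The first was held by 49 of 101 such genes lower in siCDK4-1 (48.5%) and the second by 28 of 143 lower in siCDK4-2 (19.6%). Of 152 lower over the mean of both sets, 41 held at least 1 of these words or CGGAGAA, described below, against 1676 of all 11393. Of 33 that passed as lower in each set, 5 held the first and 3 the second. The words were picked from the same libraries, so these counts are descriptive. Without genes that hold any of the 3 words, the median of the G1/S list was -0.85 over 31 genes, against -0.84 with them. That of the G2/M list was -0.95 over 25 genes, against -0.95 with them. Overlapping words also went with lower values, such as CCTTTAA (t = -13.42) and TGCCTTT (t = -12.25) in siCDK4-1 and GACATAA (t = -9.89) in siCDK4-2. Genes with these and none of the 3 words stayed in, so the medians do not show that the lists are free of seed-matched effects. The word most tied to higher values in both sets was CGGAGAA, which does not occur in the CDK4 mRNA (t = 6.81 and 6.98, adjusted p = 2.07e-08 and 1.67e-08, 255 genes, higher by 0.156 and 0.168). Both comparisons subtract the same siNC libraries, so these values are not independent, no value for unchanged groups was made, and whether the word goes with the siNC or the knockdown libraries was not tested.

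Of 11 histone genes 5 rose, while 16 of 36 genes of the G1/S list fell, and neither list was called with an estimated correlation (adjusted p = 0.165 and 0.108). A bias with transcript length could give this, since histone transcripts are short (median 834 bases), but removing the trend of log2 change on length left a median of 0.78, from 0.90, while the trend itself spanned -0.10 to 0.19. More RNA without a poly(A) tail in the knockdown libraries would raise small RNAs as well. Over 85 snRNA, snoRNA, scaRNA and misc_RNA genes the median change was 0.19 (95% bootstrap interval 0.12 to 0.44), and 2 of them passed the threshold. Both ends of the interval are positive, so their median was also higher, by less than that of the histone genes. The interval lay under the limit of 0.45, though close to it. A rule fixed before the test derived that limit from the histone median. The bootstrap drew genes from the same libraries, and whether libraries from an mRNA kit measure such RNA was not tested. This explanation is therefore not excluded. How fragments were shared between histone copies was not tested and stays open, as does a rise of polyadenylated histone transcripts in cells with less CDK4.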
